A study of Mus musculus with 8 samples.

How the data were processed

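The samples were 8 libraries of mouse genomic DNA from a chromosome conformation assay, in which crosslinked and ligated chromatin is read out as contacts of a chosen viewpoint with restriction fragments elsewhere. There were 4 cell types with 2 replicates each: embryonic stem cells grown in serum and leukemia inhibitory factor (ES), neuronal stem cells of embryonic day 14.5 cortex (NSC), differentiated cortical neurons (neuron) and the neuroblastoma cell line N2a. The neuron libraries were labelled with embryonic day 14.5 as well. Each library had 1 file per viewpoint, for 5 viewpoints and 40 files. The series' design text names the 3 viewpoints of the Pax6 locus (Paupar, Pax6P0 and Pax6P1). The Sox2 and Pou3f3 viewpoints had files of the same form and were used as loci on other chromosomes. The labels do not say whether replicates were separate cultures, so every p measures the spread between these samples only.

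Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with Bowtie to mm10. Tool versions, the restriction enzyme, the assignment of reads to fragments, any removal of duplicate reads and the interaction caller are not given in the sources used here. The deposited tables list restriction fragments with at least 1 read, and their read column holds counts, whole reads per fragment, with no normalization by the authors. The authors' column headed RPMs holds a signal and not reads scaled to a common total: in each file it was an exact power of the read count, with exponents from 0.894 to 3.49 over the 40 files. It was used only to describe the files. The authors' z column holds a score per fragment and was not tested. The authors' p and q columns hold a p value and a q value per fragment within each file, and only the q values were used. Adjacent fragments often held equal counts. Listed reads exceeded the fewest reads that could give the same counts, were each read allowed to cover a run of adjacent fragments, by a median factor of 2.23 (range 1.73 to 2.86), a ratio that exceeds 1 wherever listed fragments adjoin. On other chromosomes, where reads are sparse, a median of 88.7% of listed fragments (range 70.3% to 96.6%) had an adjacent listed fragment, and the ratio was 1.52 to 2.46. Such runs are what reads counted in several fragments would leave, though no level expected by chance was computed.

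Viewpoints were located as the longest stretch without listed fragments near the named gene. Distances are from the centre of that stretch. Negative distances and the word upstream mean lower coordinates, and downstream means higher coordinates. Listed reads were summed per library in 5 kb windows within 1 Mb of each viewpoint, leaving out 5 kb on either side. Library size was the file's total of reads on the viewpoint's chromosome beyond 5 kb, with no scaling factor, so that a window's value is a share of those reads, here called the share of cis reads and given in percent. Windows passing edgeR's filterByExpr with its minimum count of 10 were tested, 356 for Paupar, 321 for Pax6P0, 320 for Pax6P1, 366 for Sox2 and 323 for Pou3f3.

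One edgeR (4.0.16) quasi-likelihood model with robust estimation was fitted per viewpoint to all 8 libraries, with 1 coefficient per cell type and no block. It gave a test over all 4 cell types and 3 contrasts: NSC against ES, neuron against NSC, and N2a against NSC. Values of p were adjusted by Benjamini and Hochberg over the windows of 1 viewpoint and 1 contrast, with a threshold of 0.05. A permutation of 2 libraries against 2 cannot go below a two-sided p of 0.333, so none was run. The common dispersion was 0.306 to 0.535, a coefficient of variation between replicates of 55.3% to 73.1%, and tested windows held a median of 22 to 37 reads per library. Reads without molecular identifiers are not independent molecules. Ratios given against a count of 0 use a floor of 3 reads per library and take the other group at its mean. They cover the counting error of the 0 count only.

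The region 100 to 120 kb downstream of Sox2, where a known control region of Sox2 lies, was fitted with the Sox2 windows and tested alone. The stretches of the other Pax6-locus viewpoints were fitted in the same way and adjusted over 6 viewpoint pairs. Windows were grouped into bands 10 to 50, 50 to 100, 100 to 200, 200 to 500 and 500 to 1000 kb upstream and downstream, and into the windows overlapping each listed gene. These sets were tested with fry and camera of limma (3.58.1) on log CPM with a prior count of 2. Values of p were adjusted over the 3 contrasts. This was done apart for the bands of the Pax6 locus, for the bands of Sox2 and Pou3f3, and for all genes. Here fry asks whether the windows of a set moved 1 way on balance, with no comparison to other windows. Camera asks instead whether a set moved differently from the other windows. It was run without and with an estimate of the correlation between windows. Values given with an estimated correlation are those of camera. The gene lists held Rcn1, Wt1, Pax6os1, Ccdc73, Eif3m, Pax6, Elp4, Immp1l, Dnajc24, Dcdc1, Dcdc5 and Mpped2 on chromosome 2, Sox2ot, Atp11b, Dnajc19 and Fxr1 around Sox2, and Pantr1, Pantr2, Mrps9, Tgfbrap1 and Gpr45 around Pou3f3. The annotation, of the same build as the files, matched 20 of the 21 listed genes. Dcdc1 had no match, and Mpped2 and Atp11b lay beyond 1 Mb. The annotation held no strand, so the windows at both gene ends stood in for transcription start sites, and gene bodies were widened by 2 kb on both sides.

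Viewpoints, windows, contrasts, region and gene lists and the naming rule were fixed before the data were examined. Named windows were, per viewpoint and contrast, up to 5 higher and up to 5 lower windows with the largest change among those past the threshold whose 4 libraries did not overlap, and the 5 windows per viewpoint with the smallest adjusted p over all cell types. The windows at listed gene ends, the Sox2 distal region and the other viewpoints' stretches were added whatever their p. Chance alone leaves 2 against 2 libraries without overlap in 33.3% of cases.

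Alternatives fixed beforehand were edgeR's TMM factors, DESeq2 (1.42.0) size factors in the edgeR model, DESeq2's own test, no filter, 2 and 10 kb windows, 10 kb left out on either side, a range of 500 kb, replicate number as a block, and each library left out in turn. Added after the data were seen were 20 kb windows, 20 kb windows with TMM factors, the fewest reads per run of adjacent fragments, and 500 kb bins over the whole viewpoint chromosome. The authors' calls were fragments with q under 0.1 in both replicates, with q under 0.05, q under 0.01 and sharing within 5 kb as alternatives. Over the tested windows of all viewpoints, the differences between same-numbered replicates correlated from -0.0168 to 0.0482 between cell types, and within single viewpoints they reached 0.151 (Paupar). The percent of reads on the viewpoint's chromosome was higher in replicate 2 in all 20 combinations of viewpoint and cell type, by 2.54 to 20.8 points, so a shift shared by replicate number is not excluded. The 5 viewpoints were read in the same libraries, so these combinations hold only 4 replicate pairs, 1 per cell type. The main fit leaves such a shift out, and the block is given as an alternative.

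The edgeR model was tested on simulated counts with the common dispersion of each viewpoint and the mean shares and library sizes of the real libraries, for 1686 windows of which 200 were changed in NSC. It called 0 of 70 windows changed 2-fold, 3 of 65 changed 4-fold and 12 of 65 changed 8-fold (18.5%), and 0 of 1486 unchanged windows in NSC against ES. In neuron against NSC, the same counts gave 0 of 70, 6 of 65, 8 of 65 and 0 of 1486. All simulated windows of a viewpoint shared 1 dispersion, while the real fit also estimated the spread of single windows. Windows with many reads could have small standard errors there, such as 0.21 from 5 to 10 kb downstream of Pax6P1 in N2a against NSC. These shares of called windows therefore apply to windows of the common spread. In sets of 20 windows shifted 2-fold, fry called 7 of 25, and 0 of 50 unchanged sets. The simulated windows were drawn independently of each other. These shares of called sets therefore need not hold for real bands and genes, whose windows may be correlated. Other work used R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.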

Results

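Contacts of 5 viewpoints were counted in 8 mouse libraries, 2 from each of ES, NSC, neuron and N2a cells. On chromosome 2 of mm10, the Paupar viewpoint lay at 105660480 to 105662320, at an end of Paupar, a long noncoding RNA gene next to Pax6. The Pax6P0 and Pax6P1 viewpoints, at the P0 and P1 promoters of Pax6, a transcription factor gene of eye and brain development, lay at 105667489 to 105669388 and 105674040 to 105676188. The Sox2 viewpoint lay on chromosome 3 at 34647002 to 34650633, at a transcription factor gene of pluripotent and neural stem cells. The Pou3f3 viewpoint lay on chromosome 1 at 42695817 to 42699251, at a transcription factor gene of the developing brain. Summed over the 5 viewpoints, the ES libraries held 574791 and 247067 listed reads, the NSC libraries 110677 and 341036, the neuron libraries 363111 and 254435, and the N2a libraries 281950 and 367615. Single files held 18150 to 137331 listed reads (median 61397 over 40 files), of which 44.8% to 75.1% lay on the viewpoint's chromosome. All shares below are means ± SD with n = 2 libraries per cell type.

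At the Pax6 locus, the order of windows by reads correlated between cell types at values close to those between replicates. Spearman correlations across windows, which are not independent replicates, averaged 0.726 between replicates and 0.713 between cell types from Paupar. The corresponding means were 0.696 and 0.681 from Pax6P0, and 0.705 and 0.679 from Pax6P1. Between the Pax6-locus viewpoints within a library they averaged 0.694 to 0.715. All these correlations include the fall of reads with distance from the viewpoint, so their height alone does not show a shared contact profile. From Sox2 the correlations were 0.691 between replicates and 0.601 between cell types, and from Pou3f3 0.768 and 0.719. With 10 kb windows 10 of these 13 means were higher by more than the spread between pairs, at 0.748 to 0.843. The edgeR test over all cell types passed 1 window from Paupar, 0 from Pax6P0, 0 from Pax6P1, 52 from Sox2 and 15 from Pou3f3. At an unadjusted p under 0.05 these viewpoints had 42, 31, 36, 96 and 56 windows, and DESeq2 passed 8, 9, 6, 46 and 22. The Paupar, Pax6P0 and Pax6P1 counts moved with single libraries. From Paupar the count was 0 without ES replicate 1, ES replicate 2, NSC replicate 2 or N2a replicate 2, 2 without NSC replicate 1 and 4 without N2a replicate 1. From Pax6P0 it was 4 without NSC replicate 1, 5 without NSC replicate 2, 1 without N2a replicate 1 and 9 without N2a replicate 2. From Pax6P1 it was 2 without ES replicate 1, 4 without ES replicate 2, 7 without neuron replicate 1, 4 without neuron replicate 2, 2 without NSC replicate 2, 1 without N2a replicate 1 and 10 without N2a replicate 2. From Sox2 it was 23 without ES replicate 1 or ES replicate 2, 26 without neuron replicate 1, 24 without neuron replicate 2 and 79 without N2a replicate 2. From Pou3f3 it was 4 without ES replicate 1 and 9 without ES replicate 2 or neuron replicate 1.

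**Figure D1:**
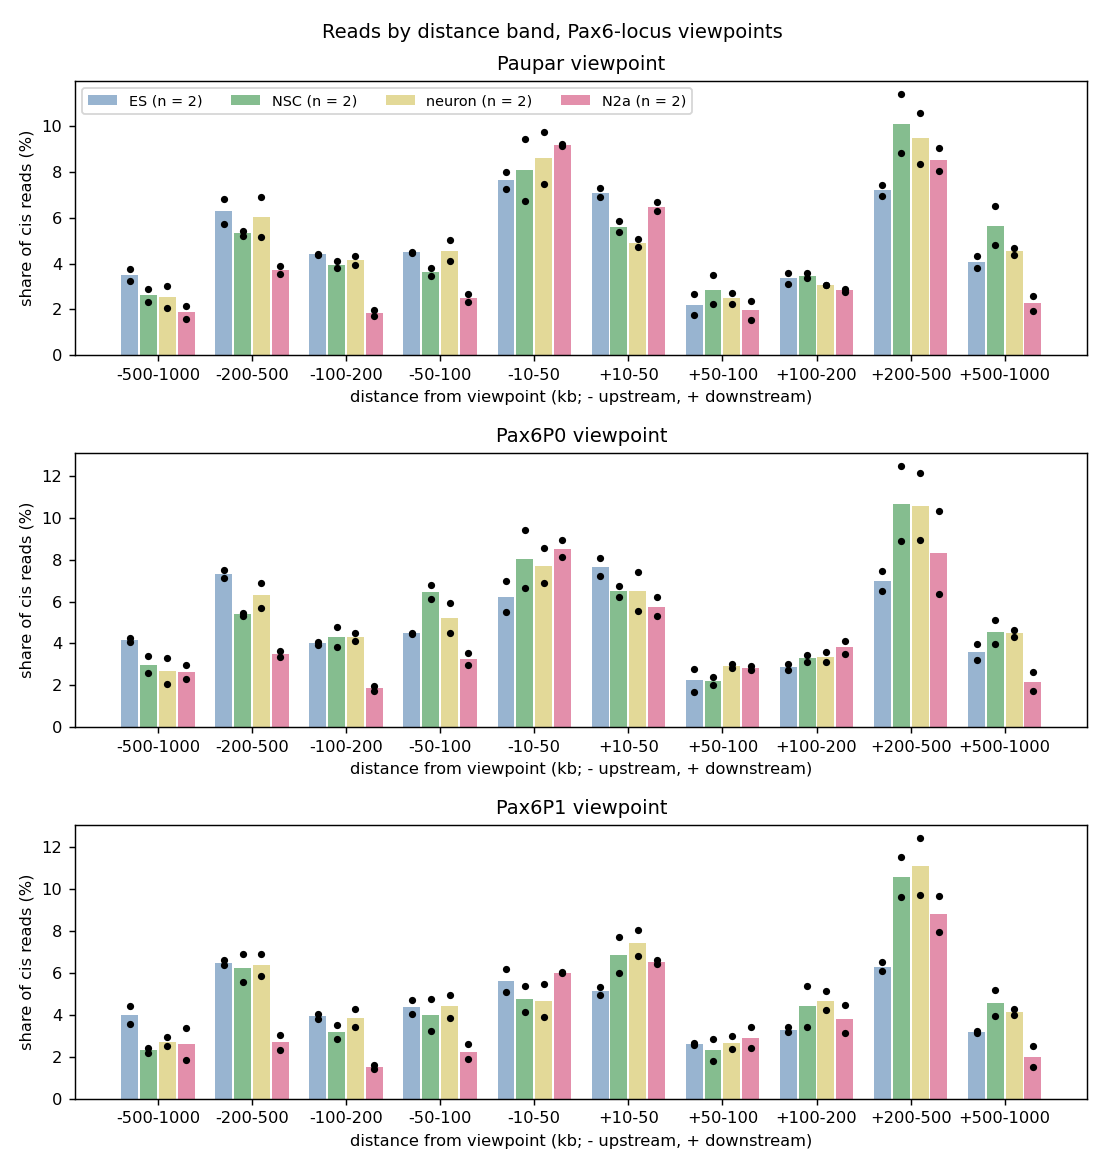
Share of cis reads (percent, y axis) in 10 distance bands (kb from the viewpoint, x axis, - upstream and + downstream) for the Paupar, Pax6P0 and Pax6P1 viewpoints. Bars are means of 2 libraries per cell type and points are the libraries; 500 to 1000 kb downstream of Pax6P1, N2a held 2.01% against 4.58% in NSC.

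NSC were compared with ES to ask how the Pax6 locus is contacted in neural against pluripotent stem cells. The Paupar viewpoint contacted the Pax6 P0 promoter more in NSC than in ES, with 1.85% ± 0.237 of cis reads in NSC, 1.05% ± 0.125 in ES, 1.46% ± 0.183 in neurons and 1.77% ± 0.0785 in N2a. The log2 change was 0.83 with a standard error of 0.26 and an adjusted p of 0.0093 over the 6 viewpoint pairs, and both NSC libraries lay above both ES libraries. Read from Pax6P0, the Paupar stretch held 3.06% ± 1.56 in NSC and 1.96% ± 0.245 in ES, with an adjusted p of 0.136. The other viewpoint pairs did not pass, and the Pax6P1 stretch held 0.419% ± 0.240 in NSC and 0.741% ± 0.0961 in ES from Paupar. Windows at Wt1, a transcription factor gene of kidney and gonad development, fell together in NSC from Paupar, where the 11 windows over the gene held 1.06% ± 0.0633 in ES and 0.473% ± 0.0217 in NSC. Their fry adjusted p was 0.0318, and camera with an estimated correlation gave an adjusted p of 0.449. From Pax6P0 Wt1 held 1.22% ± 0.163 in ES and 0.670% ± 0.303 in NSC, and from Pax6P1 1.31% ± 0.521 and 0.319% ± 0.0205, neither past the threshold by fry. Camera passed Wt1 from Paupar, Pax6P0 and Pax6P1, with adjusted p of 0.0025, 0.0125 and 5.7e-06. With an estimated correlation it passed none of these, with 0.449, 0.449 and 0.556.

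No single 5 kb window of the Pax6 locus passed in NSC against ES. Among 997 windows of the 3 viewpoints edgeR passed 0, with 54 at an unadjusted p under 0.05, and DESeq2 passed 1. Of the 30 distance bands fry passed 0, with 4 at an unadjusted p under 0.05. Camera passed 7 of them, and 0 with an estimated correlation. The bands 200 to 500 kb downstream held 7.20% ± 0.326 in ES and 10.1% ± 1.83 in NSC from Paupar, 6.99% ± 0.673 and 10.7% ± 2.55 from Pax6P0, and 6.30% ± 0.316 and 10.6% ± 1.33 from Pax6P1, with fry adjusted p of 0.486, 0.537 and 0.363. The Paupar to Pax6P0 call ended without ES replicate 2 (log2 0.71, adjusted p 0.184), without NSC replicate 2 (0.69, 0.0731) and with the fewest reads per run of fragments (0.46, 0.813), and was kept under 17 of 20 alternatives, whose adjusted p ranged from 0.0032 to 0.813 in all. The Wt1 call from Paupar ended in 6 of the 8 fits that left out a library, all but those without N2a replicate 1 or 2, with adjusted p from 0.123 to 0.249. It also ended with replicates as a block (adjusted p 0.0951), with 2, 10 and 20 kb windows (0.175, 0.0503 and 0.0712), with 20 kb windows and TMM factors (0.155) and within 500 kb (0.268). Most of Wt1 lies beyond 500 kb of Paupar, so that range does not test the whole gene. The window count became 1 without neuron replicate 1, neuron replicate 2, NSC replicate 1, N2a replicate 1 or N2a replicate 2, and 4 without NSC replicate 2.

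Neurons were compared with NSC to ask what differs after differentiation. No window, band or listed gene of the Pax6 locus passed. Of 997 windows edgeR passed 0, with 29 at an unadjusted p under 0.05, and DESeq2 passed 0 with 40. Without NSC replicate 1 edgeR passed 1. Fry passed 0 of 30 bands and 0 of 30 gene tests, each with 1 at an unadjusted p under 0.05. Elp4, whose introns hold distal enhancers of Pax6, held 10.1% ± 1.17 of cis reads in NSC and 8.56% ± 0.251 in neurons from Paupar. From Pax6P0 it held 9.82% ± 0.544 and 10.5% ± 0.0966, and from Pax6P1 11.8% ± 3.72 and 12.7% ± 1.14. The Pax6P1 stretch read from Pax6P0 held 1.36% ± 0.403 in NSC and 0.670% ± 0.184 in neurons, with an adjusted p of 0.0969. From Sox2 edgeR passed 0 of 366 windows with 13 at an unadjusted p under 0.05, and from Pou3f3 0 of 323 with 15; DESeq2 passed 0 from both, with 16 and 19. Without N2a replicate 2 the Sox2 count was 1, and without NSC replicate 2 the Pou3f3 count was 1. In simulated counts with windows changed in NSC, neuron against NSC called 0 of 70 windows changed 2-fold, 6 of 65 changed 4-fold and 8 of 65 changed 8-fold. At the common dispersion used there, most changes of these sizes would be missed.

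N2a was compared with NSC to ask how the locus is contacted in a neuroblastoma line against neural stem cells. N2a had a smaller share of cis reads within 1 Mb: 51.2% ± 3.86 against 61.0% ± 2.12 in NSC from Paupar, 49.6% ± 4.53 against 61.2% ± 5.40 from Pax6P0, and 45.0% ± 3.54 against 59.0% ± 0.877 from Pax6P1. The median log2 change of all tested windows was -0.60, -0.73 and -0.70 for Paupar, Pax6P0 and Pax6P1, and 0.06, -0.16 and -0.25 with TMM factors, so changes are read against these medians. A region of 4930527A07Rik upstream of Pax6 stood below them from 2 viewpoints. From Paupar, the window from -145 to -140 kb (105516400 to 105521399) held 0.441% ± 0.0551 in NSC, 0.413% ± 0.0181 in ES, 0.299% ± 0.0420 in neurons and 0.0699% ± 0.0233 in N2a, and fell by 2.68 on the log2 scale (SE 0.56, adjusted p 0.0017). It was also the 1 Paupar window past the test over all cell types, with an adjusted p of 0.0120. From Pax6P1, the window from -155 to -150 kb (105520114 to 105525113) held 0.446% ± 0.149 in NSC and 0.0472% ± 0.00326 in N2a, and fell by 3.23 (SE 0.65, adjusted p 0.0130). The 2 windows overlap only from 105520114 to 105521399. Both viewpoints lie close together and were read in the same libraries, so the 2 calls are not independent. No Pax6P0 window passed in this contrast.

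In all, edgeR passed 4 of 997 windows in N2a against NSC, 1 higher and 3 lower, with 161 at an unadjusted p under 0.05. The third lower window, within Pax6 from 5 to 10 kb downstream of Pax6P1, held 6.60% ± 1.94 in NSC and 3.58% ± 0.673 in N2a, fell by 0.88 (SE 0.21), and lay at -0.36 with TMM factors, against their median of -0.25. The higher window, 965 to 970 kb downstream of Pax6P1, rested on 1 library, with 176 and 3 reads in N2a and 0 in both NSC libraries. The split between higher and lower depended on the scaling: TMM factors passed 9 windows, 8 higher and 1 lower, DESeq2 passed 27, 15 higher and 12 lower, and 20 kb windows passed 34, 1 higher and 33 lower. Without N2a replicate 2 edgeR passed 26, and without NSC replicate 2 it passed 8. The Paupar call of the upstream region ended without NSC replicate 2 (log2 -2.54, adjusted p 0.113) and without N2a replicate 2 (-2.36, 0.0555), with DESeq2 size factors (-1.97, 0.0561) and with the fewest reads per run of fragments (-2.18, 0.282). Its call over all cell types ended without ES replicate 1 (adjusted p 0.0612), ES replicate 2 (0.0631), NSC replicate 2 (0.140) or N2a replicate 2 (0.18), with TMM factors (0.141), with DESeq2 size factors (0.220), by the DESeq2 test (0.0518) and with the fewest reads (0.388). The Pax6P1 call ended without NSC replicate 2 (-2.84, 0.0710), with TMM factors (-2.77, 0.0676) and with DESeq2 size factors (-2.61, 0.0895). The window within Pax6 lost its call without NSC replicate 1 (-0.54), N2a replicate 1 (-1.09) or N2a replicate 2 (-0.70), and the window on 1 library lost it without NSC replicate 1, NSC replicate 2 or N2a replicate 1. Both also lost it with TMM factors (adjusted p 0.615 and 0.0676) and with DESeq2 size factors (0.768 and 0.0895), and the window within Pax6 by the DESeq2 test (0.774) and with the fewest reads (0.331).

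Some bands of the Pax6 locus were lower in N2a than in NSC. Fry passed 8 of 30, all lower in N2a, with 12 at an unadjusted p under 0.05, and no band 200 to 500 kb downstream or 500 to 1000 kb upstream passed from any of the 3 viewpoints. The 3 bands 500 to 1000 kb downstream were among them, with 5.66% ± 1.19 in NSC and 2.27% ± 0.458 in N2a from Paupar, 4.56% ± 0.811 and 2.17% ± 0.657 from Pax6P0, and 4.58% ± 0.870 and 2.01% ± 0.679 from Pax6P1. In these bands ES lay between NSC and N2a, at 4.08% ± 0.393, 3.60% ± 0.544 and 3.17% ± 0.0855. Upstream, the band from 100 to 200 kb fell from Paupar (3.96% ± 0.218 to 1.85% ± 0.213), those from 50 to 100, 100 to 200 and 200 to 500 kb from Pax6P0, and that from 200 to 500 kb from Pax6P1 (6.23% ± 0.972 to 2.68% ± 0.509). Dcdc5, a gene of the far downstream side, fell from Paupar, with 6.75% ± 0.641 in NSC and 3.51% ± 0.434 in N2a (fry adjusted p 0.0318). ES held 4.55% ± 0.218 over Dcdc5, so NSC lay above ES as well. Camera passed 7 of the 30 bands. With an estimated correlation it passed none of the bands above and not Dcdc5. The adjusted p was then 0.351 for the band 500 to 1000 kb downstream of Pax6P1 and 0.449 for Dcdc5. With TMM factors 2 bands passed, 500 to 1000 kb downstream of Pax6P1 lower and 10 to 50 kb downstream of Paupar higher, with adjusted p of 0.328 and 0.444 with an estimated correlation, and Dcdc5 had an adjusted p of 0.105. With replicates as a block none of the 8 bands and not Dcdc5 passed, with adjusted p from 0.0667 to 0.0894 and of 0.0951. From Pax6P0, the bands 50 to 100 and 200 to 500 kb upstream and 500 to 1000 kb downstream also ended with 10 kb windows, 20 kb windows and the fewest reads. The Pax6P0 band 200 to 500 kb upstream ended with 2 kb windows too, and that of Pax6P1 with 20 kb windows. All 8 ended with 20 kb windows and TMM factors. The band count was 3 without neuron replicate 1 or neuron replicate 2 and 0 without each of the other 6 libraries. Dcdc5 lost its call without any 1 of the ES, neuron or NSC libraries (mean log2 change from -1.52 to -0.97). It also lost it with 2 and 10 kb windows (adjusted p 0.175 and 0.0503), with 20 kb windows and TMM factors (0.0840) and within 500 kb (0.823). Most of Dcdc5 lies beyond 500 kb of Paupar too, so that range does not test the whole gene.

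At Sox2, the distal region from 100 to 120 kb downstream (34748817 to 34768816), which holds a known enhancer of Sox2 in embryonic stem cells, was contacted most in ES. It held 3.95% ± 0.186 of cis reads in ES, 0.797% ± 0.0705 in NSC, 0.746% ± 0.325 in neurons and 0.796% ± 0.353 in N2a. The share in ES was 4.96 times that in NSC, and both ES libraries lay above the 6 others. In NSC against ES it fell by 2.31 on the log2 scale (SE 0.42), with an edgeR p of 6.6e-08 for this region alone. Over 20 alternatives the log2 change ranged from -2.49 to -1.79, with a largest p of 0.00155. The windows from 110 to 115 kb and 115 to 120 kb of this region passed among all windows too, at -2.96 (SE 0.60, adjusted p 3.4e-04) and -3.21 (SE 0.78, adjusted p 0.0033). These window calls ended without ES replicate 2 or NSC replicate 1 for the first, with adjusted p of 0.0597 and 0.0571, and without ES replicate 1, ES replicate 2 or NSC replicate 1 for the second, with adjusted p from 0.0842 to 0.270. Both also ended with the fewest reads per run of fragments (-1.94, adjusted p 0.334, and -2.91, 0.0524), which ended the call of the first over all cell types too (0.270); that of the second ended without ES replicate 1 (0.0760).

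Farther from Sox2, NSC held more contacts than ES in several gene-free regions. The windows from -415 to -410, -405 to -400, -360 to -355, -270 to -265 and -205 to -200 kb were higher in NSC, the last 4 by 2.65, 3.13, 2.81 and 2.36 on the log2 scale and the first from 0.0433% ± 0.0459 to 0.515% ± 0.05 of cis reads. The window from -360 to -355 kb (34288817 to 34293816) held 0.0554% ± 0.0400 in ES, 0.502% ± 0.126 in NSC, 0.592% ± 0.193 in neurons and 0.0528% ± 0.0146 in N2a (SE 0.73, adjusted p 0.0018). The window from 830 to 835 kb (35478817 to 35483816) had the smallest p over all cell types at Sox2 (adjusted p 1.2e-09), with 0.739% ± 0.556 in ES, 2.90% ± 0.738 in NSC, 1.49% ± 0.147 in neurons and 0.341% ± 0.0734 in N2a, changes of 1.98 in NSC against ES and -3.09 in N2a against NSC. By bands, 200 to 500 kb upstream rose from 5.63% ± 0.0883 in ES to 13.3% ± 0.837 in NSC, and 50 to 100 and 100 to 200 kb downstream fell from 5.35% ± 0.423 to 2.09% ± 0.401 and from 10.2% ± 0.349 to 4.06% ± 0.729, with fry adjusted p of 0.0300, 0.0300 and 0.0316. With an estimated correlation the adjusted p of these bands was 0.176, 0.182 and 0.210. In all, edgeR passed 9 of 366 windows in NSC against ES, 7 higher and 2 lower. TMM factors passed 11, 7 higher and 4 lower, and DESeq2 16, 10 higher and 6 lower. The count was 0 without NSC replicate 1, 1 without ES replicate 2, 4 without ES replicate 1, 15 without NSC replicate 2, 16 without N2a replicate 1 and 18 without N2a replicate 2. All 5 upstream windows lost their call without ES replicate 2 (adjusted p 0.379 to 0.596) and without NSC replicate 1 (0.0571 to 0.488). With the fewest reads per run of fragments, all but that at -360 kb lost it (log2 2.09 to 2.99, adjusted p 0.0612 to 0.391). Those at -270 and -205 kb also lost it without ES replicate 1 (0.270 and 0.332), and those at -270 and -405 kb without neuron replicate 1 (0.0928 and 0.0898) or neuron replicate 2 (0.104 and 0.0608). At 830 kb the NSC against ES call ended without ES replicate 1 (adjusted p 0.332) or NSC replicate 1 (0.119). The band calls held without NSC replicate 2, and those of the upstream band and the band from 50 to 100 kb also without NSC replicate 1, and ended without each of the other libraries, with adjusted p from 0.0672 to 0.246. All 3 ended with replicates as a block (0.0759 to 0.0871), the upstream band with 2 kb windows (0.0832) and the band from 100 to 200 kb with the fewest reads (0.116). With TMM factors all 3 passed, and the band 200 to 500 kb downstream of Sox2 also fell (0.0464), with adjusted p of 0.0723 to 0.185 for these 4 bands with an estimated correlation.

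**Figure D2:**
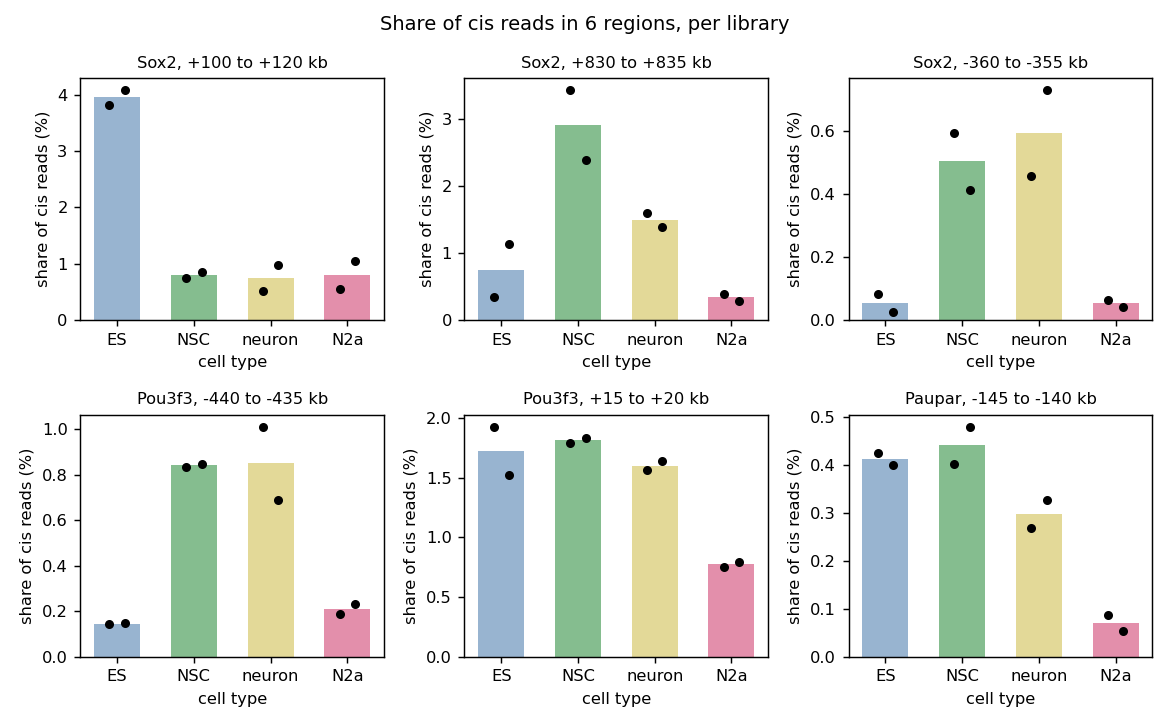
Share of cis reads (percent, y axis) per cell type (x axis) in 6 regions named by viewpoint and distance. Bars are means of 2 libraries and points are the libraries; the Sox2 region at +100 to +120 kb held 3.95% in ES, and the Pou3f3 window at -440 to -435 kb held 0.840% in NSC and 0.146% in ES.

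In N2a against NSC, the shares of cis reads 200 to 500 kb upstream and 500 to 1000 kb downstream of Sox2 fell, and 2 of the 24 windows over Sox2ot, a long noncoding RNA gene that overlaps Sox2, were higher. Sox2ot as a whole did not pass by fry in the main fit (adjusted p 0.155), and rose with TMM factors (median log2 1.36, fry adjusted p 0.0048, and 0.316 with an estimated correlation). Against the other windows, camera passed Sox2ot in the main fit (adjusted p 1.1e-05), and not with an estimated correlation (0.449). The share within 1 Mb was 50.3% ± 4.00 in N2a and 74.2% ± 4.74 in NSC, and the median log2 change of all windows was -0.86, or 0.04 with TMM factors. The window from 925 to 930 kb (35573817 to 35578816) held 0.551% ± 0.0301 in NSC and 0.0266% ± 0.0185 in N2a, and fell by 4.30 (SE 0.79, adjusted p 1.1e-05). The window from -370 to -365 kb fell by 4.46 (SE 0.98), and these 2 calls were kept under each alternative in which the window was tested. The windows from -480 to -475 and -750 to -745 kb fell by 4.56 and 4.52. That from -475 to -470 kb held 0.0424% ± 0.0160 in NSC (3 and 25 reads) and 0 reads in N2a. Its NSC mean was 3.85 times a floor of 3 reads per library in N2a, with no allowance for error in NSC. The Sox2ot windows from -40 to -35 and -20 to -15 kb rose by 2.37 (SE 0.69) and 2.12 (SE 0.63), the first from 0.148% ± 0.0619 to 0.792% ± 0.520. A window of Ttc14 from -850 to -845 kb rose by 4.18 (SE 1.43). The window at the Dnajc19 gene end, from -570 to -565 kb, held 0.217% ± 0.0577 in NSC and 0.0153% ± 0.00244 in N2a, and fell by 3.80 (SE 1.06, adjusted p 0.0081). The bands 200 to 500 kb upstream (13.3% ± 0.837 to 4.73% ± 0.212) and 500 to 1000 kb downstream (19.3% ± 1.04 to 7.33% ± 0.159) fell, with fry adjusted p of 0.0157 and 0.0388, and adjusted p of 0.182 and 0.593 with an estimated correlation. With TMM factors these bands still fell (0.0050 and 0.0464), and 4 bands close to Sox2 rose, 10 to 50 and 50 to 100 kb upstream (0.0464 and 0.0174) and downstream (0.0174 and 0.0050). With an estimated correlation the adjusted p was 0.0973 and 0.254 for the lower and 0.150 to 0.303 for the higher bands. So fry passed 2 bands of Sox2 and Pou3f3 in the main fit, both lower, and 6 with TMM factors, 4 higher and 2 lower. Camera passed 4 in each of these fits, and 0 with an estimated correlation.

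In all, edgeR passed 37 of 366 Sox2 windows in N2a against NSC, 3 higher and 34 lower. TMM factors passed 24, 13 higher and 11 lower, and DESeq2 40, 24 higher and 16 lower. The count was 22 without ES replicate 1, ES replicate 2 or N2a replicate 1, 20 without neuron replicate 1 or NSC replicate 1, 21 without neuron replicate 2, and 23 without NSC replicate 2. Without NSC replicate 1 or N2a replicate 1, the windows from -40 kb (log2 2.04 and 1.48) and -20 kb (1.80 and 1.73) lost their calls. The window from -480 kb lost it without neuron replicate 1, NSC replicate 1 or N2a replicate 1 (adjusted p 0.0504 to 0.0678), that from -750 kb without those or neuron replicate 2 (0.0545 to 0.516), and the Dnajc19 window without NSC replicate 2 (0.0608). The window from -475 kb was kept only without NSC replicate 1, and that of Ttc14 only without N2a replicate 2, with adjusted p up to 0.123 and 0.438 in the other fits that left out a library. With TMM factors the windows from -475, -480 and -750 kb and that of Dnajc19 had adjusted p of 0.0984, 0.0557, 0.0733 and 0.0733, and with DESeq2 size factors 0.107, 0.0530, 0.0720 and 0.0922. The window from -475 kb also lost its call by the DESeq2 test (0.0639). With the fewest reads the windows from -475, -750 and -20 kb and that of Ttc14 lost theirs (0.0508 to 0.175), with replicates as a block those from -750 kb and of Ttc14 (0.0922 and 0.0903), and with no filter that of Ttc14 (0.0512). The upstream band lost its call in 6 and the downstream band in 7 of the 8 fits that left out a library, with adjusted p up to 0.121 and 0.246. Both ended with replicates as a block (0.0759 and 0.0859), and the downstream band with 2 kb windows (0.0832).

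At Pou3f3, regions far upstream were contacted more in NSC than in ES. The window from -440 to -435 kb, in Gm28175 (42257534 to 42262533), held 0.146% ± 0.000258 in ES, 0.840% ± 0.00724 in NSC, 0.850% ± 0.227 in neurons and 0.210% ± 0.0292 in N2a. It rose by 2.52 in NSC against ES (SE 0.45, adjusted p 3.7e-06) and fell by 2.00 in N2a against NSC (SE 0.44, adjusted p 0.0019). In Gm29260, the windows from -890 to -885, -880 to -875, -810 to -805 and -805 to -800 kb rose by 2.20, 3.09, 2.54 and 2.00, the second from 0.0780% ± 0.0113 to 0.674% ± 0.313. All tested windows had a median log2 change of -0.33 in this contrast, and -0.24 with TMM factors. In neurons a further Gm29260 window, from -955 to -950 kb, held 0.457% ± 0.279 against 0.0954% ± 0.0490 in NSC and 0.0648% ± 0.0141 in ES, past the test over all cell types (adjusted p 1.3e-04) and not past the neuron contrast (adjusted p 0.339). Close to the gene, the window from 15 to 20 kb, within Gm46091 and over an end of Pantr2, a long noncoding RNA gene next to Pou3f3, held 1.81% ± 0.0261 in NSC and 0.774% ± 0.0280 in N2a, and fell by 1.23 (SE 0.29, adjusted p 0.0038). By bands, 500 to 1000 kb downstream fell in NSC from 2.14% ± 0.0395 in ES to 1.02% ± 0.167, with a fry adjusted p of 0.0300 and an adjusted p of 0.210 with an estimated correlation. The band count by fry depended on the scaling: at Sox2 and Pou3f3 together, 4 bands passed in NSC against ES, 1 higher and 3 lower, and 9 with TMM factors, 2 higher and 7 lower. The Pou3f3 bands passing with TMM factors alone were 500 to 1000 kb upstream, higher (0.0464), and 10 to 50, 100 to 200 and 200 to 500 kb downstream, lower (0.0174, 0.0464 and 0.0380). With an estimated correlation their adjusted p was 0.0723, 0.827, 0.711 and 0.123. In this contrast camera passed 7 bands of Sox2 and Pou3f3 in the main fit and 7 with TMM factors, and 0 with an estimated correlation.

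In all, edgeR passed 6 of 323 Pou3f3 windows in NSC against ES, all higher in NSC, and 2 in N2a against NSC, both lower in N2a. TMM factors passed 10 higher and 0 lower in NSC against ES, and DESeq2 12 higher and 1 lower. The NSC against ES windows from -890, -880 and -440 kb were kept under each alternative in which they were tested. The window from -805 kb lost its call without ES replicate 2 (log2 1.76, adjusted p 0.152), and the windows from -810 and -805 kb with the fewest reads per run of fragments (0.151 and 0.102), as did the call from -810 kb over all cell types (0.189). The N2a against NSC call from -440 kb ended without N2a replicate 1 (-1.86, 0.0947), and that from 15 kb without ES replicate 1, ES replicate 2, N2a replicate 1 or N2a replicate 2 (adjusted p 0.0683 to 0.115), and both with the fewest reads (0.154 and 0.504). That count was 0 without N2a replicate 1, 1 without ES replicate 1, ES replicate 2 or N2a replicate 2, and 4 without NSC replicate 1. The call over all cell types from -955 kb ended without neuron replicate 1 (0.319), and that from -890 kb without ES replicate 1 (0.0681). The downstream band ended in 6 of the 8 fits that left out a library, with adjusted p up to 0.398, with replicates as a block (0.0875), with 20 kb windows and TMM factors (0.0766) and with the fewest reads (0.933).

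**Figure D3:**
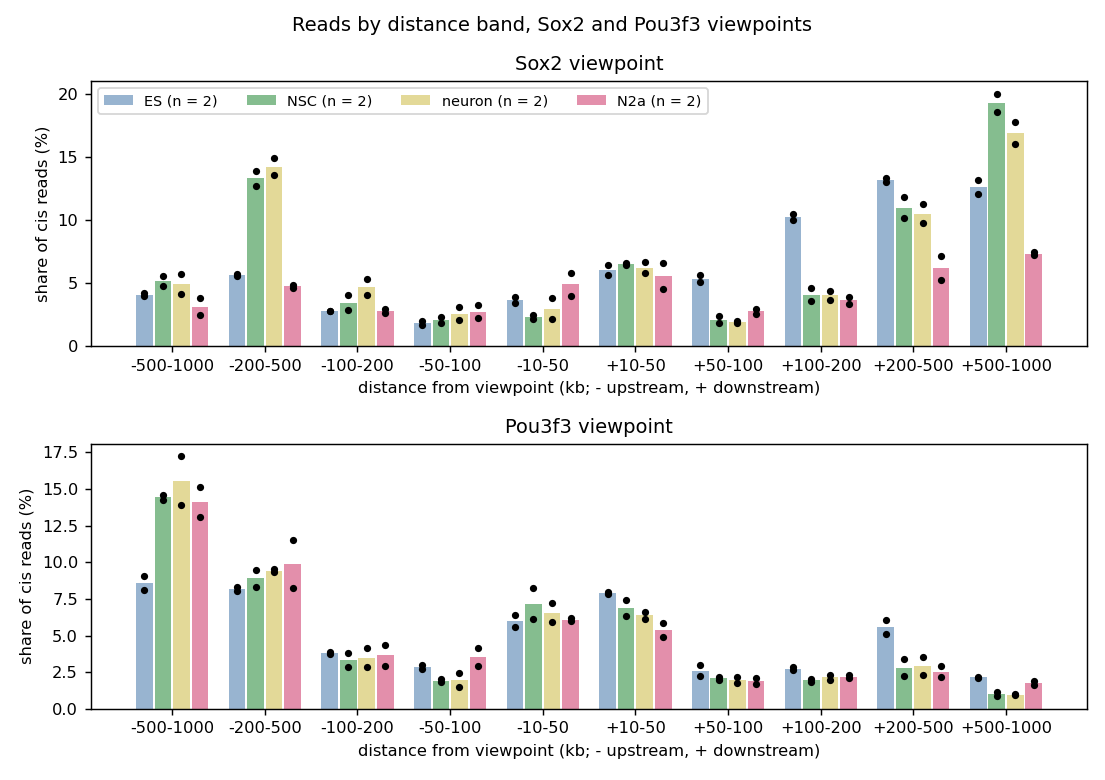
Share of cis reads (percent, y axis) in 10 distance bands (kb from the viewpoint, x axis, - upstream and + downstream) for the Sox2 and Pou3f3 viewpoints. Bars are means of 2 libraries per cell type and points are the libraries; 200 to 500 kb upstream of Sox2, NSC held 13.3% and ES 5.63%.

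Over the listed genes, most did not pass. Gene tests by fry at the Pax6-locus viewpoints passed 1 of 30 in NSC against ES (Wt1 from Paupar), 0 of 30 in neuron against NSC and 1 of 30 in N2a against NSC (Dcdc5 from Paupar), with 10, 1 and 6 at an unadjusted p under 0.05. Both calls are among the gene tests that single libraries ended: the total was 0 without any 1 of the ES, neuron or NSC libraries, 2 without N2a replicate 1 and 3 without N2a replicate 2. At Sox2 and Pou3f3 fry passed 0 of 8 in each contrast, with 3, 0 and 4 at an unadjusted p under 0.05, and with TMM factors 1 of 8 in N2a against NSC, Sox2ot, higher in N2a. In the main fit camera passed 5, 0 and 3 of 30 gene tests at the Pax6 locus, and 1, 0 and 1 of 8 at Sox2 and Pou3f3. The 5 in NSC against ES were Wt1 from each viewpoint, lower, and Dcdc5 from Paupar and Pax6P1, higher (adjusted p 0.0175 and 0.0064). With an estimated correlation camera passed 0, in the main fit and with TMM factors. Fxr1, which codes for an RNA-binding protein, held 0.843% ± 0.121 in NSC and 0.204% ± 0.116 in N2a from Sox2, with an adjusted p of 0.141. Pax6 itself held 9.74% ± 0.313 in ES, 9.26% ± 0.397 in NSC, 8.24% ± 0.654 in neurons and 10.1% ± 0.0162 in N2a from Paupar. Of 71 windows at gene ends, 59 distinct, 2 passed in N2a against NSC (Dnajc19 and Pantr2) and 0 in the other contrasts, and the counts adjusted over the list alone were 2, 0 and 0.

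The authors' own calls lay mostly close to the Pax6-locus viewpoints. Fragments with a q under 0.1 in both replicates numbered 124 in ES, 89 in NSC, 102 in neurons and 102 in N2a over the 3 viewpoints, and 83.1%, 97.8%, 92.2% and 85.3% of them lay within 10 kb. The farthest was an ES fragment from Paupar at -53.9 kb, in Pax6os1 (105607338 to 105607682), a noncoding RNA gene that overlaps Paupar. From Sox2, 9 ES fragments from 34754820 to 34760008, at 109 kb, and 1 at 117 kb (34765575 to 34766829) lay in the distal region, and single ES fragments were called at 124, 461 and 754 kb. Fragments at 831 kb (35479600 to 35479955 in NSC) were called in NSC and in neurons, and the farthest N2a fragment lay 10.2 kb away. Single libraries held 131 to 222 called fragments per cell type, so agreement between replicates sets these counts. No test of differences between cell types was made on them.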

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

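The tests in this part were chosen after the results were seen. Fragments on other chromosomes than the viewpoint's were not used in the comparisons, and the authors' calls among them stood out. In both replicates of a cell type, 14 distinct fragments on other chromosomes had a q under 0.1, and most of them adjoined another of the 14. Of 20 combinations of viewpoint and cell type, the chromosome 8 fragments at 10960473 to 10960518 and 10960521 to 10960544 were called in 16 each, that at 116546603 to 116548276 in 15 and that at 10960547 to 10960705 in 10. These 4 fragments were each called from viewpoints on 3 chromosomes. Those from 10960473 to 10960705 adjoin and form a single stretch. Reads may be counted in several adjacent fragments, so the calls within this stretch are not separate. A repeated or easily misaligned sequence was not tested, and neither was any biological explanation.

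From the Pou3f3 viewpoint, reads collected at its paralogs Pou3f1 and Pou3f2 on chromosome 4, which code for related transcription factors. Per 100000 reads on other chromosomes, the Pou3f1 fragments held 936 ± 435 and the Pou3f2 fragments 359 ± 123 (n = 8 libraries). From the other 4 viewpoints the means were 73.7 to 122 and 83.8 to 108. The Pou3f1 fragment at 124657117 to 124658696 was called in 7 combinations, 4 from Pou3f3 and the others from Paupar and Pax6P0. Of the reads within 50 kb of these sites, a median of 98.0% lay within 2 kb from Pou3f3 (range 78.9% to 100%, 16 values) and 91.7% from the other 4 viewpoints (51.4% to 100%, 64 values), a gap of 6.27 points with overlapping ranges. This concentration is therefore not particular to the paralog viewpoint and does not decide for or against shared or captured paralog sequence. A contact between the loci in the nucleus predicts more reads 2 to 50 kb away as well. From Pou3f3 their rate was 0.833 times the mean of the other viewpoints at Pou3f1 and 2.42 times at Pou3f2, from 18 and 46 reads over 8 libraries. At Pou3f1 the predicted rise was not seen, with 11.2 ± 14.2 reads per 100000 from Pou3f3 against a mean of 13.5 from the others. At Pou3f2 the rate was 29.3 ± 31.2 against 12.1, a gap within the spread between libraries. A contact that raises the reads around both sites was therefore not seen. With so few reads, and sites that differ, the explanations cannot be told apart for the sites together and both stay open.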

How the results depend on the processing

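The 20 kb windows, the 20 kb windows with TMM factors and the fewest reads that could give the listed counts were chosen after the data were seen, and the other alternatives before. The lower contact of the Sox2 distal region in NSC than in ES kept its direction and stayed past its threshold under all 20 alternatives, from -2.49 to -1.79 on the log2 scale, and from -2.40 to -2.22 when 1 library was left out. The higher Paupar to Pax6P0 contact in NSC kept its direction in all 20 and its call in 17. Named windows kept their calls in 367 of 467 comparisons with an alternative, windows named from the test over all cell types in 157 of 170, bands in 114 of 261 and genes in 14 of 38, with 0 reversed. Mean correlations of profiles moved beyond their spread in 10 of 26 comparisons, all higher with 10 kb windows, and shares by band in 66 of 400, all higher (1.04 to 1.11 times) with the first 10 kb left out. With 1 library left out, which these totals of correlations and shares leave aside, 0 of 104 correlations and 0 of 400 shares moved. The totals of windows, bands and genes include the fits with 1 library left out. Windows named for a contrast were chosen without overlap between libraries, so leaving out 1 library could hardly reverse them. Calls over all cell types have no direction to reverse. For these windows the count of 0 reversed is therefore no separate evidence. Window counts moved more. With TMM factors, the count over all cell types was 8 from Paupar, N2a against NSC passed 9 Pax6-locus windows, NSC against ES passed 10 Pou3f3 windows, and 2 Pax6-locus bands passed. With DESeq2 size factors in the edgeR fit these were 7, 7, 14 and 2, and 5 genes passed. The DESeq2 test passed 8, 9 and 6 windows over all cell types from Paupar, Pax6P0 and Pax6P1, 1 Pax6-locus window in NSC against ES and 27 in N2a against NSC, and 16 Sox2 and 13 Pou3f3 windows in NSC against ES. With no filter, 2 windows passed over all cell types from Paupar, 6 from Pax6P1, and 1 Pax6-locus window in NSC against ES. With 2 kb windows the counts over all cell types were 0 from Paupar, 3 from Pax6P1, 18 from Sox2 and 7 from Pou3f3, NSC against ES passed 1 Pax6-locus and 2 Sox2 windows, N2a against NSC passed 2 Pax6-locus windows, and 0 genes passed. With 10 kb windows N2a against NSC passed 11 Pax6-locus windows and NSC against ES 11 Pou3f3 windows, and 5 bands and 0 genes passed. Within 500 kb, 4 Pou3f3 windows passed over all cell types and 1 in NSC against ES, and 5 bands and 0 genes passed. That range holds no band beyond 500 kb and only a small part of Wt1 and Dcdc5. With replicates as a block, which pairs libraries by replicate number, 1 window passed over all cell types from Pax6P0 and 3 from Pax6P1, 1 Pax6-locus window in NSC against ES and 8 in N2a against NSC, and 0 bands and 0 genes. With 20 kb windows, 10, 11 and 7 windows passed over all cell types from Paupar, Pax6P0 and Pax6P1, 34 Pax6-locus windows in N2a against NSC, 14 Pou3f3 windows in NSC against ES, and 5 bands. Adding TMM factors to them gave 2 from Paupar, 4 from Pax6P0 and 26 from Sox2 over all cell types, 14 Sox2 and 13 Pou3f3 windows in NSC against ES, 0 bands and 1 gene. With the fewest reads, 28 Sox2 and 7 Pou3f3 windows passed over all cell types, N2a against NSC passed 1 Pax6-locus window, NSC against ES 2 Sox2 windows, and 5 genes passed. The cause of these moves was not tested. Leaving out the first 10 kb moved no count by more than 1.5 times. With 1 library left out, where the lone library of a cell type is assumed to vary like the other groups, the counts over all cell types ranged from 0 to 4 from Paupar, 0 to 9 from Pax6P0, 0 to 10 from Pax6P1, 23 to 79 from Sox2 and 4 to 20 from Pou3f3. The Pax6-locus counts ranged from 0 to 4 in NSC against ES, 0 to 1 in neuron against NSC and 3 to 26 in N2a against NSC. NSC against ES at Sox2 ranged from 0 to 18, bands from 0 to 3 and genes from 0 to 3. Fragments called from a single replicate numbered 184 to 195 in ES, 131 to 154 in NSC, 159 to 170 in neurons and 201 to 222 in N2a, above the counts shared by both replicates. Stricter q thresholds and counting calls within 5 kb as shared kept these shared counts within 1.5 times. DESeq2's own test was not run for bands and genes, and windows of 2, 10 and 20 kb give no value for a named 5 kb window. Tested windows held a median of 22 to 37 reads per library and varied by 55.3% to 73.1% between replicates. With the common dispersion of each viewpoint, the simulated test called 12 of 65 windows changed 8-fold in NSC against ES and 8 of 65 in neuron against NSC. Window counts therefore miss most changes in windows of that spread. The parts of depth and spread in this were not separated.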

Other observations

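The 500 kb bins and the tests of explanations in this part were chosen after the data were seen. Beyond the range of the comparisons, the region 1 to 2 Mb upstream of Pou3f3 held a larger share of reads in NSC, neurons and N2a than in ES, with no test of the whole region. It held 8.30% ± 0.581 of cis reads in ES, 15.2% ± 2.58 in NSC, 15.6% ± 1.86 in neurons and 18.2% ± 0.331 in N2a (n = 2 libraries each). In 500 kb bins, edgeR passed 3 of 338 bins in NSC against ES, 2 higher and 1 lower, with 39 at an unadjusted p under 0.05. The bin at 41197534 to 41697533 on chromosome 1 held 4.06% ± 0.242 in ES, 8.05% ± 0.809 in NSC and 8.55% ± 0.764 in neurons, and rose by 0.99 on the log2 scale in NSC (SE 0.18, adjusted p 5.9e-04). The next bin upstream, 40697534 to 41197533, rose from 4.24% ± 0.339 to 7.12% ± 1.77 (0.75, adjusted p 0.0428), and 40197534 to 40697533 fell from 1.48% ± 0.127 to 0.563% ± 0.0345 (-1.40, adjusted p 0.0428). These bins were not refitted with 1 library left out. At the other viewpoints NSC against ES passed 1 bin from Paupar, higher, and 2 from Sox2, 1 higher and 1 lower, and N2a against NSC passed 1 from Paupar, higher.

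At Sox2, N2a reads spread far along chromosome 3. The share within 1 Mb was 50.3% ± 4.00 in N2a and 74.2% ± 4.74 in NSC, while 5 to 20 Mb away N2a held 21.8% ± 1.68 and NSC 6.68% ± 0.608. In 500 kb bins, edgeR passed 30 of 290 in N2a against NSC, 25 higher and 5 lower, with 75 at an unadjusted p under 0.05. More random ligation in the N2a libraries predicts a lower cis percent in the Sox2 files. The N2a values were 55.8 and 69.6, against 57.4 and 66.9 in NSC, so no drop was seen beyond the spread between libraries. Both N2a values lay above a cutoff of 40. That cutoff was set after the data were seen and lay below every file (lowest 44.8), so it does not decide. A single junction on 1 side of Sox2 in the N2a genome predicts a rise on 1 side. The share 5 to 20 Mb away was 4.04 times that of NSC upstream and 2.66 times downstream, which argues against it as the source of all these reads. From 1 to 2 Mb the ratio was 3.15 upstream and 0.876 downstream, as a junction upstream needs. The upstream share was 4.11% ± 0.0347 in N2a, 1.31% ± 0.750 in NSC, 1.21% ± 0.336 in neurons and 1.95% ± 0.0932 in ES. The bin with the smallest p (33148817 to 33648816) held 0.398% ± 0.0544 in NSC, 1.00% ± 0.0225 in ES, 0.546% ± 0.0475 in neurons and 2.86% ± 0.151 in N2a. It was higher in N2a than in NSC (log2 2.85, SE 0.32, adjusted p 6.7e-11) and lower in NSC than in ES (-1.34, SE 0.30, adjusted p 0.0026), so NSC itself was low in this bin. A junction upstream therefore stays open for this part. A change of copy number or several rearrangements in this cell line, and a difference in chromatin between the cell types, may each contribute; they stay open and were not tested.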
